A study of Mus musculus with 8 samples.

How the data were processed

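Gene expression was measured in 8 cultures of mesenchymal stem cells (MSC) grown from mouse bone marrow, 4 from NOD mice and 4 from BALB/c mice. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with DNase treatment, checked on a Bioanalyser and turned into biotinylated cRNA for single-colour Illumina arrays. The series design states that each culture came from the pooled marrow of at least 5 mice and that cells were taken at passage 4, while the sample titles read as single mice. It also describes a culture step with interleukin-1 beta, but no array is labelled as treated and all 8 were taken as untreated. The strain label of each sample set its group. The series text numbers the NOD samples before the BALB/c samples and the labels run the other way, so the labels were used.

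The deposited table of the whole series gave, for each of 46628 probes and each array, the mean bead signal intensity, which per the file headers had not been normalized. Median signal intensity was 58.2, 74.9, 61.0 and 56.5 in BALB/c cultures 1 to 4. In NOD cultures 1 to 4 it was 75.8, 74.8, 78.6 and 68.7. On each array 36.3% to 39.5% of the probes other than controls and numeric accessions had a detection p-value under 0.05. The deposited detection p-value ranks a probe's signal against the array's negative controls, and its steps correspond to 1603 negative controls. The median of these controls was 49.4, 59.9, 48.8 and 48.2 in BALB/c cultures 1 to 4. In NOD cultures 1 to 4 the median was 59.9, 58.6, 57.8 and 52.1. A second table held the authors' normalized intensity of the same arrays on a linear scale. Its values kept the rank order of the signals on every array (Spearman correlation of 1) and, in NOD culture 2, differed from the raw signal by at most 0.005, so that array appears to have been the target of the normalization. The medians of its columns were 73.6, 74.0, 76.6 and 74.8 in BALB/c cultures 1 to 4 and 75.2, 74.8, 75.7 and 75.3 in NOD cultures 1 to 4. The authors' method, the array model, the scanner software and any BeadChip assignment are not given in the sources used here.

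The tables pair no probe with a gene symbol. Probe identifiers of one kind embed a zero-padded number, and 82.6% of 11857 such numbers were found among the gene IDs of the RefSeq table of mouse assembly GRCm38.p6, against 11.3% of 16482 unpadded 5-digit numbers. These numbers were therefore read as gene IDs. The reading was tested on gene families. Of probes so named, 7 of 343 olfactory receptor probes were detected, against 78 of 89 cytosolic ribosomal protein probes and 18 of 21 proteasome probes. With accession-named probes and the Cdkn2a probe, 9806 probes carried a name and 8107 genes had at least 1. Other probes stayed unnamed here and were counted only as probes. A second way of naming, through clone synonyms, was tried and dropped because such probes followed gene-ID probes of the same gene poorly.

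Values were computed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with the mean and SD of the negative controls that limma infers from the detection p-values, an offset of 16 was added, and arrays were quantile normalized on the log2 scale. On each array 4 or 5 probes with a signal of at least 10173 carried a detection p-value above 0 but below 1 step of the negative controls. Read as deposited, these p-values made limma take these bright probes for negative controls and raised the inferred background SD from 14.2 to 30.2 up to 198 to 382, which compressed the differences of dim probes. They were set to 0 before the background fit. This correction was made only after the results of a first fit with the p-values as deposited had been seen. That first fit called 356 genes, 136 of them at least 2-fold, 1194 probes and 6 gene lists, and 261 of its genes are among the 386 reported. It is given among the alternatives. A fit with a robust background had also been seen by then.

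Control, reporter, ribosomal, retroviral repeat and numeric-accession probes were left out of the tests. Probes detected on at least 4 of the 8 arrays entered the fit, 17745 in all, and the probe with the highest mean stood for a gene, which gave 4225 named genes. NOD was compared with BALB/c by limma's lmFit and eBayes with Benjamini-Hochberg adjustment over all 17745 probes, and an adjusted p under 0.05 was called. Differences are NOD minus BALB/c on the log2 scale, with the standard error (SE) of the fit, and levels are means ± SD of 4 arrays. A fold given as "at least" sets the brighter strain against, on each array of the other strain, the higher of the dim probe's value and the lowest value of a detected probe, because the probe was detected on no array of the other strain. It is a bound computed under the background fit used here, and such folds are smaller with the detection p-values as deposited. Where a probe was detected on some arrays of the dimmer strain, the fold or difference is of fitted values, part of them at background. The offset makes folds of dim genes too small. The number of arrays limits the precision, and depth does not apply.

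Of 29 gene lists fixed before the data were examined, 23 had the 3 tested members needed for a test. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists, and again with an estimated correlation, with fry and with an exact permutation test over the 70 assignments of the 8 arrays. The smallest 2-sided p that this exact test can give is 0.0286. The genes named were, by a rule also fixed before the data were examined, the 10 with the largest and the 10 with the smallest difference among called genes whose arrays did not overlap between strains, up to 4 called members of each list, and 13 genes named whatever their values. The result of 1 gene that this rule names is not reported here. On simulated data of 17745 probes, the fit of NOD against BALB/c called 19% of 2-fold and 64% of 4-fold changes, and 3.49% of its calls were unchanged probes. In that draw 100 probes were changed 2-fold and 100 were changed 4-fold, fewer than the 1511 called in the data. The rates depend on the share changed and need not hold there. In a separate draw of 1 probe per gene, camera called 0 lists when none was shifted and ranked a shifted list first. All simulated values were drawn independently, with the same SD in both strains. The draw therefore does not test camera where members of a list vary together, as in the cell cycle list (estimated correlation 0.61).

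Alternatives covered the background correction, the normalization, the authors' normalized intensities, the offset, the filter on dim probes, the probe standing for a gene, the variance model (statmod 1.5.0 for the robust form), array weights, the replicate number as a block and each culture left out. Chosen after seeing the data were the detection p-values as deposited, a background fit from the median and the median absolute deviation of the negative controls, the removal of BALB/c cultures 2 and 3 or 2 and 4 together (the latter also with the probes tested on all 8 arrays kept), and the exact permutation test of lists.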

Results

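MSC are adherent stromal cells of the bone marrow that can form bone, fat and cartilage and that dampen immune responses. The NOD mouse develops autoimmune diabetes, and BALB/c is a strain that does not. The design asked how MSC of NOD mice with normal blood glucose differ in gene expression from those of BALB/c mice of the same age, with BALB/c as the reference. There were 4 cultures of each strain, each on 1 array.

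The 8 arrays separated by strain along the first principal component, which held 47.4% of the variance. The NOD cultures resembled each other, with correlations between arrays of 0.927 to 0.985 across the tested probes. Those of the BALB/c cultures ran from 0.842 to 0.983. BALB/c cultures 1 and 4 were alike, and cultures 2 and 3 stood apart from them and from each other. Between strains the correlations were 0.812 to 0.906, a range that overlaps that within BALB/c. BALB/c culture 2 correlated better with NOD culture 1 than with any BALB/c culture (at most 0.872), and BALB/c culture 3 correlated best with NOD culture 2 (0.906). The raw median signal of BALB/c culture 2 (74.9) lay among those of NOD (68.7 to 78.6). Those of the other BALB/c cultures were 56.5 to 61.0. An unnamed batch that goes with the strains was not tested. The median SD of a probe was 0.29 within NOD and 0.48 within BALB/c on the log2 scale.

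**Figure D1:**
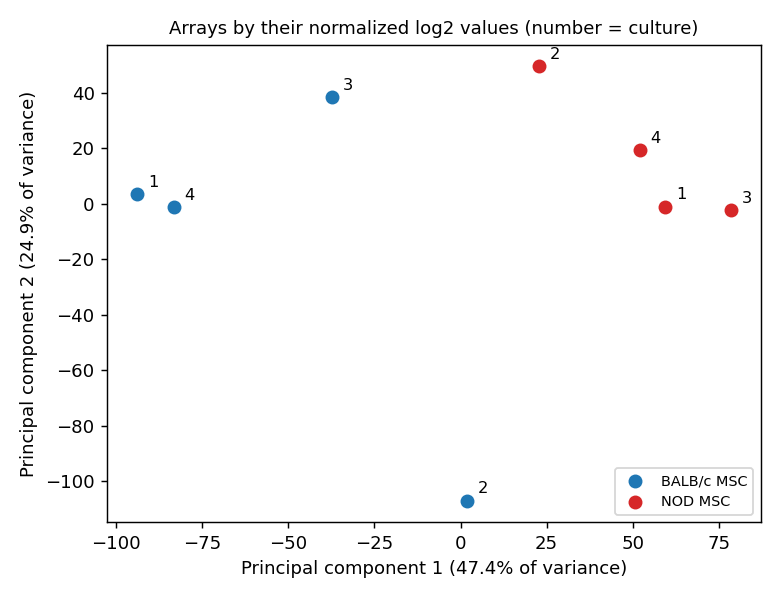
Each point is 1 array, placed by the first (47.4% of variance) and second (24.9%) principal component of the normalized log2 values of the tested probes, in arbitrary component units and coloured by strain. The 4 NOD arrays lie to the right of all 4 BALB/c arrays, and BALB/c culture 2 lies apart on the second component.

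In NOD MSC, 175 named genes were higher and 211 were lower than in BALB/c MSC, 386 of 4225 tested. Of these, 316 differed at least 2-fold, 155 higher and 161 lower. Among all 17745 probes, named or not, 738 were higher and 773 lower. In 381 of the 386 genes the 4 NOD arrays all lay on one side of the 4 BALB/c arrays, as they did in 800 of all 4225 genes. For a single gene chance gives 2.86%. Genes vary together across the arrays, and the count was not made for other splits, so it does not measure an excess over chance. With median scaling in place of quantile normalization the split of calls turned to 229 higher and 148 lower, and the median difference of all probes moved to 0.15. With the detection p-values as deposited, which was the first fit made, the counts were 356 genes, 136 of them at least 2-fold, and 1194 probes, with 261 genes shared. That fit lost 13 of the 51 named genes called here: Parm1, Arl5a, Apol9a, Egfl7, Alpl, Irf1, Cd274, Il18, Irak1, Tlr1, Igfbp6, Cdkn2a and Cyp51. It also gave a fold smaller by over 1.5 times for 33 of the 51 and larger by that much for none. The folds of dim genes, the "at least" folds among them, thus depend on setting the p-values below 1 step to 0. The robust background fit, which also had them at 0, gave folds of 149 for Tmem14c, 96.4 for Sspn, 90.4 for Ptn, 50.7 for H2-D1 and 15.3 for Gbp2b. The count of 386 genes moved by over 1.5 times without any single culture. It was 161, 797, 640 and 173 without BALB/c cultures 1, 2, 3 and 4, and 179, 219, 190 and 134 without NOD cultures 1, 2, 3 and 4. Named genes that lost their call numbered 18, 1, 2 and 16 without BALB/c cultures 1, 2, 3 and 4, and 18, 18, 21 and 25 without NOD cultures 1, 2, 3 and 4. These are of 44 that had a value without a BALB/c culture and 47 without a NOD culture, since the rest of the 51 fell out at the detection filter.

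The osteocalcin genes Bglap2, Bglap and Bglap3, which encode a protein secreted by bone-forming cells, were 74.8-fold, 72.2-fold and 59.3-fold higher in NOD MSC (Bglap2 12.36 ± 1.45 against 6.14 ± 1.26, adjusted p = 0.00218). Their probes were detected on 3, 2 and 2 of the 4 BALB/c arrays. They are near-identical copies, and their probes may not tell them apart. Ptn, the growth factor pleiotrophin, was at least 62.6-fold higher (11.28 ± 0.88 in NOD, adjusted p = 3.68e-05) and was detected on no BALB/c array. The same held for Pdrg1, at least 44.6-fold higher, and Nat8, at least 20.9-fold higher. Il1rl1, which encodes the interleukin-33 receptor ST2, was 30.6-fold higher at 13.11 ± 1.12 against 8.18 ± 1.69 (difference 4.94 ± 0.85 SE, adjusted p = 0.00963). The collagen gene Col8a2 was detected on 1 of 4 BALB/c arrays and was 10.03 ± 1.05 in NOD (difference 4.56 ± 0.48 SE, adjusted p = 0.000666). The prolactin family gene Prl2c2, detected on 3 of 4 BALB/c arrays, was 24.2-fold higher. Prl2c2 spread widely among BALB/c cultures (SD 2.61), and its call was lost in 10 of 24 other fits. Trbv31, a T cell receptor beta segment detected on 2 of 4 BALB/c arrays, was 53.2-fold higher, while the T cell gene Cd3e was detected on no array. The folds with the detection p-values as deposited were 24.9, 18.0 and 17.2 for Bglap2, Bglap and Bglap3, 12.8 for Ptn, 8.91 for Pdrg1, 3.96 for Nat8, 4.82 for Col8a2 and 15.5 for Trbv31.

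Tmem14c, a mitochondrial membrane protein used in heme synthesis, was at least 123-fold lower in NOD MSC, where no array detected it (12.42 ± 0.38 in BALB/c, adjusted p = 6.74e-07). Sspn, the sarcospan gene, was at least 52.8-fold lower. The classical MHC class I gene H2-D1 was 50.4-fold lower, at 5.66 ± 0.49 against 11.32 ± 0.77 (difference -5.66 ± 0.41 SE, adjusted p = 7.30e-05). It was detected on 2 of 4 NOD arrays by 1 tested probe, and its sequence differs between MHC haplotypes. Parm1 was at least 32.6-fold lower (call lost in 6 of 18 other fits), with BALB/c culture 3 at 6.83 and the other three at 11.53 to 11.92. The interferon-induced GTPase Gbp2b, detected on 2 of 4 NOD arrays, was 15.4-fold lower. Arl5a and Armh4 were at least 11.2-fold and 9.81-fold lower, and the calcium-binding protein gene Sri was 10.9-fold lower. Apol9a was 10.8-fold lower and lost its call in 13 of 25 other fits. Dctn4, a dynactin subunit, was 12.1-fold lower by its brightest probe (-3.59, adjusted p = 1.04e-05), but its second probe read 0.75 with an adjusted p of 0.178. In the fit with the detection p-values as deposited the folds were 28.9 for Tmem14c, 12.1 for Sspn, 12.6 for H2-D1, 9.02 for Parm1, 3.22 for Gbp2b, 2.53 for Arl5a, 2.09 for Armh4, 6.98 for Sri and 6.09 for Apol9a.

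**Figure D2:**
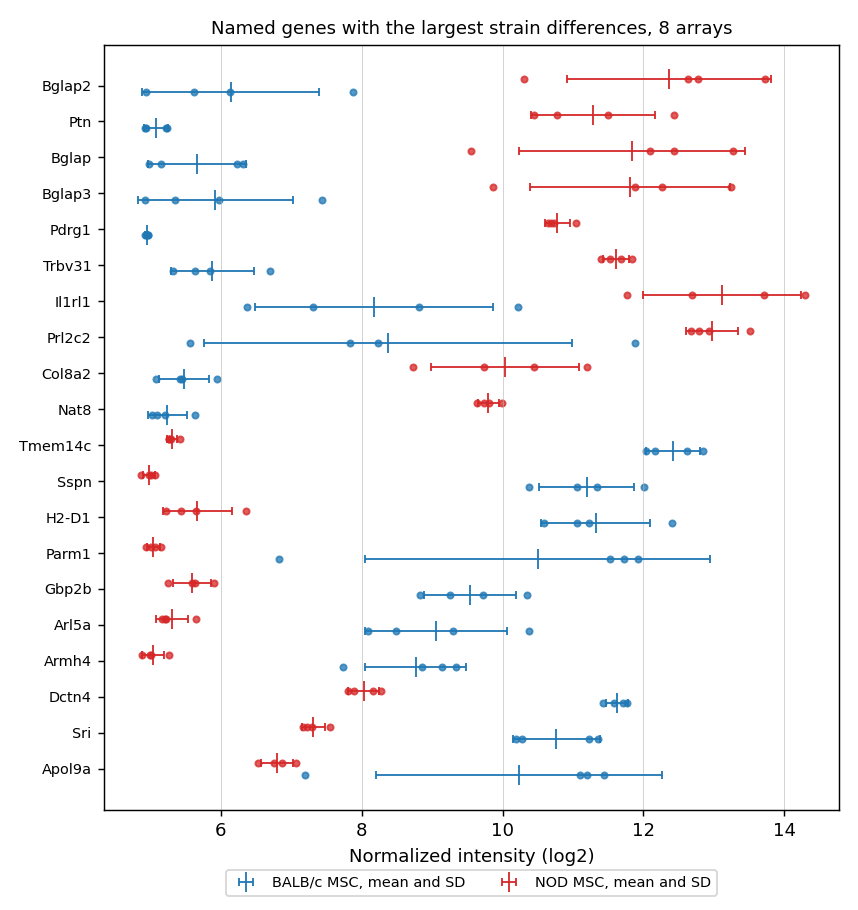
Normalized log2 intensity (horizontal axis) of the 20 named genes with the largest differences in each direction (vertical axis). Points are single arrays, ticks and bars are the mean and SD of 4 arrays per strain. By this choice the 4 NOD and the 4 BALB/c points of each gene do not overlap.

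Cd274, which encodes the inhibitory ligand PD-L1, was lower in NOD MSC. Its level was 5.47 ± 0.35 in NOD, where 1 of 4 arrays detected it, and 7.43 ± 0.51 in BALB/c, where all 4 did (difference -1.97 ± 0.30 SE, adjusted p = 0.00486). The call was absent with the detection p-values as deposited (-0.32, adjusted p = 0.0707) and with the replicate number as a block, and over 22 alternatives its adjusted p ran from 1.43e-05 to 0.0707. Among 8 tested immunomodulatory mediators, Tgfb3 was 2.85-fold and the inhibitory ligand Cd200 2.05-fold higher, with calls lost in 8 and 5 of 25 other fits. Adjusted over the list alone, 3 mediators were higher and 1 lower. The list as a whole did not pass (camera adjusted p = 0.573).

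Interferon-stimulated genes were lower in NOD MSC by camera (mean difference -1.08, adjusted p = 0.0195; adjusted p = 0.374 with an estimated correlation). Of 9 tested, 3 fell and none rose, also when adjusted over the list alone. These were the antiviral gene Mx2 (difference -2.83, detected on 1 of 4 NOD arrays), the transcription factor Irf1 (3.58-fold) and the GTPase Igtp (3.41-fold). Irf1 stood near the threshold (adjusted p = 0.0491) and was lost in 13 of 25 other fits, and Igtp in 7. Without BALB/c culture 2 the list was not called (adjusted p = 0.0764), nor without BALB/c cultures 2 and 4 (0.297, where Mx2 fell out at the detection filter, and 0.132 with the same probes kept). The list was also lost among probes detected on all 8 arrays (0.0788), with array weights (0.0961) and without BALB/c cultures 2 and 3 (0.497). Over all alternatives its adjusted p ran from 0.00312 to 0.497. The macrophage gene Cd68 had a difference of the same sign but was not called, detected on all 4 BALB/c arrays and on no NOD array (difference -2.08 ± 0.58 SE, adjusted p = 0.0614). Within BALB/c the 2 peaked in different cultures. The list mean, relative to all arrays, was highest in culture 2 (1.13), where Cd68 was 6.89. Cd68 was highest in culture 4 (9.09), where the list mean was 0.38. Of 11 tested MHC class I and peptide loading genes, 2 were lower, H2-D1 and the immunoproteasome subunit Psmb10 (3.16-fold, adjusted p = 0.00181), and the same 2 adjusted over the list alone. H2-T23, a nonclassical class I gene named here after its values were seen, read -0.60 (adjusted p = 0.188) by its brightest probe and -5.37 (adjusted p = 7.91e-06) by its second probe. B2m, the shared light chain of class I molecules, read -0.14 ± 0.16 SE (adjusted p = 0.619). The class I list did not pass (adjusted p = 0.206), but it did without BALB/c culture 1 (0.0397) or 4 (0.0288). In the MHC class II list, 1 of 3 tested genes was lower, H2-Ab1, by at least 3.17-fold. It was read by 1 tested probe, and a sequence difference between the strains under that probe was not tested. Adjusted over the list alone, 1 gene was higher and 1 lower. That list did not pass either (adjusted p = 0.573). Differences with the detection p-values as deposited were -0.28 for H2-Ab1, -0.52 for Mx2 and -0.93 for Igtp.

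The interleukin-1 and Toll-like receptor list held calls in both directions. Beside the higher Il1rl1, the signalling kinase Irak1 was 2.78-fold lower and the receptor Tlr1, detected on 1 of 4 NOD arrays, was lower (difference -1.14), among 9 tested genes. Adjusted over the list alone, 1 was higher and 3 were lower (camera adjusted p = 0.206, fry 0.0108, mean difference -0.00, median -0.64). Irak1 and Tlr1 lost their calls in 8 of 25 and 13 of 22 other fits, with adjusted p of 8.02e-05 to 0.150 and 0.000176 to 0.179. They read -0.49 and -0.14 with the detection p-values as deposited. Of 7 tested cytokines and chemokines, Il18 was 2.40-fold lower and lost its call in 11 of 25 other fits. Adjusted over the list alone 1 was higher and 1 lower (camera adjusted p = 0.910). Camera's direction for this list and its median (-0.24) were negative and its mean (0.20) positive.

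**Figure D3:**
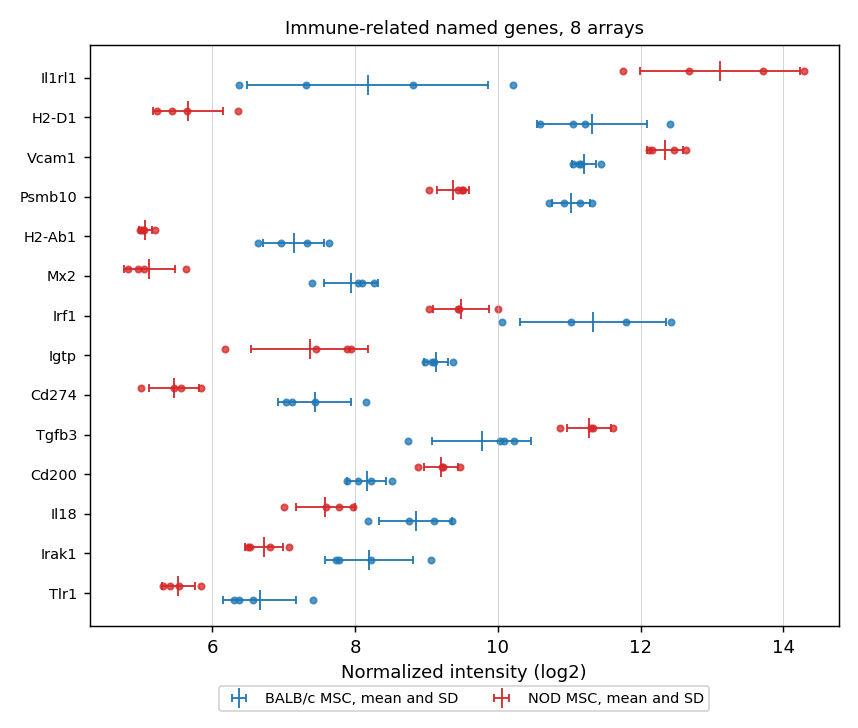
Normalized log2 intensity (horizontal axis) of named genes from the immune-related lists and of Vcam1 (vertical axis). Points are single arrays, ticks and bars are the mean and SD of 4 arrays per strain. Cd274 averages 5.47 in NOD and 7.43 in BALB/c.

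Osteoblast lineage genes were higher in NOD MSC (mean difference 2.51, camera adjusted p = 0.00847; adjusted p = 0.374 with an estimated correlation). Of 7 tested, 4 rose and none fell, also when adjusted over the list alone: Bglap2, Bglap, the alkaline phosphatase gene Alpl (7.51-fold) and the type I collagen gene Col1a2 (2.32-fold). Both osteocalcin copies count here, and the median difference of the list was 1.22. Among probes detected on all 8 arrays, which leave both copies out, its mean was 1.09 and the list was not called (adjusted p = 0.164). Alpl and Col1a2 lost their calls in 12 and 9 of 25 other fits, and with the detection p-values as deposited Alpl was 4.73-fold higher. Extracellular matrix genes were also higher (mean difference 0.76, adjusted p = 0.0195; adjusted p = 0.374 with an estimated correlation), with 11 of 12 differences positive. Col6a3 rose 3.23-fold and Col5a1 1.66-fold, with calls lost in 6 and 9 of 25 other fits, and adjusted over the list alone 2 genes were higher and 1 lower. Wnt and BMP signalling genes were higher (mean difference 1.26, adjusted p = 0.0285; adjusted p = 0.374 with an estimated correlation). Of 8 tested, the secreted ligands Wnt10b (6.99-fold) and Wnt5a (6.29-fold) rose and none fell, and 4 rose adjusted over the list alone. Their folds were 2.49 and 2.46 with the detection p-values as deposited, and the call of Wnt10b was lost in 6 of 24 other fits. Without BALB/c culture 2 the matrix and Wnt lists were not called (adjusted p = 0.0559 and 0.0587). In all, the Wnt list lost its call in 9 of 25 other fits and the matrix list in 4. The Wnt list was lost without BALB/c culture 3 (0.0978) and with the detection p-values as deposited (0.0679). It was also lost with array weights (0.0864) and among probes detected on all 8 arrays (0.295). Median scaling lost both the Wnt and the matrix list (0.0516 each), and array weights also the matrix list (0.0961). The osteoblast list was also lost without BALB/c cultures 2 and 3 (0.0981). Over all alternatives the adjusted p of the osteoblast, matrix and Wnt lists ran from 0.00187 to 0.164, 0.00236 to 0.176 and 0.00800 to 0.295.

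Cell cycle genes were higher in NOD MSC (mean difference 1.73, adjusted p = 0.000362; adjusted p = 0.436 with an estimated correlation, and 0.0508 by fry). All 12 tested members had a positive difference, but over all genes only the thymidine kinase gene Tk1 passed (5.05-fold, adjusted p = 0.0392; 2.99-fold with the detection p-values as deposited), and 8 passed adjusted over the list alone. Tk1 lost its call in 10 of 25 other fits (adjusted p 2.48e-05 to 0.126). The list mean, relative to the mean of all arrays, was -1.80, -0.30, 0.50 and -1.86 in BALB/c cultures 1 to 4 and 0.70 to 1.21 in the NOD cultures. BALB/c culture 4, with the lowest mean, also had the most leukocyte probes detected, 6 of 14. The cell cycle inhibitor Cdkn2a, read by a probe for the p16 transcript, was detected on 1 of 4 NOD arrays and was lower there (difference -3.12 ± 0.47 SE, adjusted p = 0.00463). Its call was absent with the detection p-values as deposited (-0.94, adjusted p = 0.0922) and kept in the other 21 fits (adjusted p from 3.85e-05). It was the single call among 4 tested senescence and p53 genes, also adjusted over the list alone (camera adjusted p = 0.406).

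Hypoxia and glycolysis genes were lower in NOD MSC (mean difference -0.60, adjusted p = 0.0123; adjusted p = 0.436 with an estimated correlation). All 11 differences were negative. Egln3, an oxygen-sensing hydroxylase, fell 2.50-fold (1.52-fold with the detection p-values as deposited, call lost in 1 of 25 other fits), and 4 members fell adjusted over the list alone. This list lost its call without BALB/c culture 2 (adjusted p = 0.0858, range over alternatives 0.00110 to 0.132). It was also lost without BALB/c cultures 2 and 3 (0.0793) and without 2 and 4 (0.109, and 0.132 with the same probes kept). BALB/c cultures 2 and 4 had the most of the macrophage gene Lyz2 (11.42 and 9.85), and a part of leukocytes in this list's difference was not tested. Cholesterol synthesis genes were higher (mean difference 0.87, adjusted p = 0.0285; adjusted p = 0.641 with an estimated correlation, and 0.239 by fry). Of 11 tested, 2 rose, the demethylase Cyp51 (3.64-fold) and the pathway's transcription factor Srebf2 (2.92-fold), and 1 fell. Cyp51 and Srebf2 lost their calls in 9 and 2 of 25 other fits. The second probe of Cyp51 was also higher (2.92, adjusted p = 0.0267), and that of Srebf2 was not called (0.75, adjusted p = 0.123). Adjusted over the list alone, 4 were higher and 1 lower. Without NOD culture 3 the list was not called (adjusted p = 0.129, range 0.00119 to 0.129). The call was also lost with median scaling (0.0839) and with no filter on dim probes (0.0559).

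**Figure D4:**
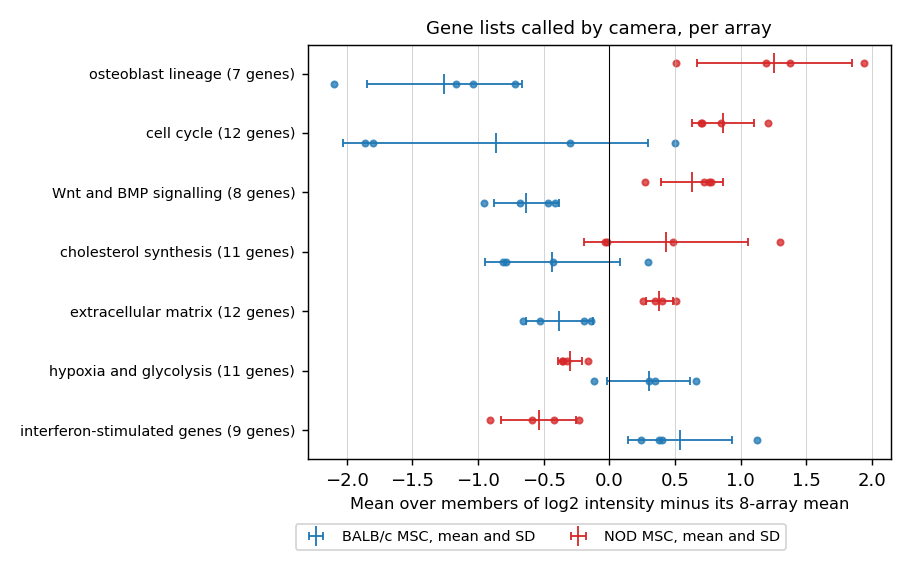
For the 7 gene lists called by camera (vertical axis), the mean over members of log2 intensity minus each gene's mean over 8 arrays (horizontal axis). Points are single arrays, ticks and bars are the mean and SD of 4 arrays per strain. In the cell cycle list, BALB/c cultures 1 and 4 lie at -1.80 and -1.86 and the other two at -0.30 and 0.50.

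Growth and niche factors were not called as a list (camera adjusted p = 0.129, fry 0.00906). Of 10 tested, the binding proteins Igfbp3 (7.18-fold, or 3.80-fold with the detection p-values as deposited) and Igfbp4 (3.82-fold) rose and Igfbp6 (3.33-fold) fell, and adjusted over the list alone 4 were higher and 1 lower. Igfbp3, Igfbp4 and Igfbp6 lost their calls in 7, 8 and 16 of 25 other fits. Among 6 tested MSC surface markers the adhesion molecule Vcam1 was 2.20-fold higher (adjusted p = 0.00945, lost in 3 of 25 other fits), also over the list alone. Cd44 (0.27 ± 0.26 SE, adjusted p = 0.550) and Eng (-0.65 ± 0.65 SE, adjusted p = 0.569) did not pass the test. The Cd44 probe was dim (5.68 ± 0.39 in NOD and 5.41 ± 0.33 in BALB/c), detected on 3 NOD arrays and 1 BALB/c array. Its value therefore says little about a difference in Cd44. The adipocyte list had 1 call of 6, Apoe (7.45-fold higher, or 4.69-fold with the detection p-values as deposited), and the protease and inhibitor list 1 of 7, Timp3 (2.25-fold higher, with a second probe higher by 2.33, adjusted p = 0.0338). Apoe and Timp3 lost their calls in 4 and 9 of 25 other fits. Adjusted over the list alone the adipocyte list held 1 higher, and the protease list 1 higher and 1 lower. The oxidative stress list had 1 call of 9, Sod1 (1.57-fold lower, lost in 14 of 25 other fits), also over the list alone. The camera adjusted p of the surface marker, adipocyte, protease and oxidative stress lists was 0.406, 0.573, 0.573 and 0.848.

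Markers of other cells were mostly undetected. The granulocyte, mast cell, lymphoid and erythroid lists had no tested gene, and Ptprc, the pan-leukocyte gene, was detected on no array. Of 14 macrophage and pan-leukocyte probes, 3, 2, 1 and 6 were detected in BALB/c cultures 1 to 4 and 0, 0, 1 and 1 in NOD cultures 1 to 4. Macrophage lysozyme, Lyz2, stood at 7.36, 11.42, 5.20 and 9.85 in BALB/c cultures 1 to 4 and at 5.57, 4.92, 8.08 and 6.66 in NOD cultures 1 to 4 (difference -2.15 ± 1.28 SE, adjusted p = 0.330). Adjusted over the list alone 1 of the 2 tested macrophage genes, Cd68, was lower in NOD, and none passed over all genes. The endothelial list had 1 tested gene, Egfl7, at least 1.84-fold higher in NOD. With the detection p-values as deposited it was not called (difference 0.11, adjusted p = 0.152), and the call was lost in 8 of 20 other fits (adjusted p 0.000341 to 0.152). Xist, read from the inactive X chromosome of female cells, was detected on all 8 arrays (0.53 ± 0.39 SE, adjusted p = 0.428). The probe of the class I gene H2-K1 was detected on no array, and Pdcd1lg2, Tgfb1, Il10, Il1r1, Ly6a, Cxcr4 and Thy1 had no probe named here.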

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

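In this part the tests of single cultures and of leukocytes were chosen only after the lists' results had been seen, and the tests of second probes and of other splits before.

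Among 130 groups of 4 arrays examined, 12 held 1 array far from the other three, where chance gives about 1 in 20, or 6.5. In BALB/c culture 3 the values were 6.83 for Parm1 (others 11.53 to 11.92), 7.19 for Apol9a (others 11.11 to 11.43), 8.08 for Col1a2 (others 9.27 to 9.38), 8.74 for Tgfb3 (others 10.04 to 10.22) and 10.05 for Eng (others 7.13 to 7.37). The same culture had list means of -1.64 for contractile genes and -0.68 for matrix proteases. BALB/c culture 2 had list means of -0.29 for MHC class II, 1.60 for senescence genes and -1.67 for immediate early genes. In NOD culture 3 Psmb10 was 9.03 (others 9.44 to 9.52), and in NOD culture 1 the Wnt and BMP list mean was 0.27 (others 0.72 to 0.77).

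Outside the comparison, 146 probes carry numeric accessions that no table used here names. Of these, 14 were detected on all 4 NOD arrays and on no BALB/c array, 1 showed the reverse and 1 was detected on all 8. Several of the 14 share an accession number, so they may not be 14 separate sequences. Their "at least" folds ran from 1.68 to 92.5. Among other probes with these numbers, 1 detected on 3 BALB/c arrays was 12.94 ± 0.33 in NOD against 5.80 ± 0.52, and some were detected on no array. The probe detected on all 8 was also brighter in NOD (13.51 ± 0.20 against 8.25 ± 0.66). The probe with the reverse pattern was dim in both strains (5.33 ± 0.17 in NOD and 6.09 ± 0.35 in BALB/c). None of these differences was tested.

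A sequence difference between the strains under a probe could mimic a difference in expression. For 35 genes called at least 2-fold with a second detected probe, that probe's difference was a median of 0.708 times that of the first (bootstrap 95% interval 0.331 to 0.993), and 28 went the same way. Only 16 of the 35 second probes were themselves called in the same direction, and 0 in the opposite. The median ratio argues against variants under the probe as the whole account of such genes as a group, but not for each gene. For differences of at least 8-fold only 3 genes had a second probe, with a median ratio of 0.386, so a variant and a true difference cannot be told apart there. H2-D1, which differs in sequence between MHC haplotypes, and Dctn4, whose second probe went the other way, are among the genes this leaves open, as is the class I gene H2-T23, whose 2 probes read -0.60 and -5.37. The class II gene H2-Ab1, with 1 tested probe, stays open too.

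The higher cell cycle list in NOD may rest on few BALB/c cultures. The mean difference nearest 0 when 1 culture was left out was 1.39 ± 0.68 (SE), without BALB/c culture 4, against 1.73 with all. A fall to 0.5 of the full value lies within that error, so a single culture and an untested strain difference both stay open. Camera at its preset correlation kept the call of this list in all 25 other fits (adjusted p up to 0.00802). All of these fits assume a correlation of 0.01, where the estimate for this list was 0.61, so they add no support for the call. With the estimated correlation camera gave an adjusted p of 0.436. BALB/c cultures 1 and 4 had the 2 lowest values (-1.80 and -1.86, against -0.30 and 0.50 in cultures 2 and 3). They were not left out together, so this pair as the source also stays open. Leukocytes diluting the stromal cells of these 2 cultures, which also had the most leukocyte probes detected (3 and 6 of 14), would lower their matrix genes as well, but against NOD the matrix list differed there by -0.55 ± 0.06 (SE) and the cell cycle list by -2.69, which argues against such dilution as the whole account in these cultures. In BALB/c culture 2, with the most Lyz2, the lists differed from NOD by -0.91 ± 0.26 and -1.17 ± 1.17 (SE), so dilution and a strain difference in proliferation cannot be told apart on this 1 array.

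The size of the lower interferon list in NOD did not rest on 1 culture, as the difference nearest 0 was -0.88 ± 0.15 (SE), without BALB/c culture 2, against -1.08 with all, although the call was then lost (adjusted p = 0.0764). Without BALB/c cultures 2 and 4, which had the most Lyz2 (11.42 and 9.85), the same 9 members differed by -0.86 ± 0.16 (SE), which argues against leukocytes in those cultures as the whole account. With 2 BALB/c arrays left the list was not called (adjusted p = 0.132), and the SE rests on few arrays. The 2 cultures were picked by Lyz2 alone, and other macrophage genes ranked the cultures otherwise. Cd68 (9.09 and 7.93) and C1qb (8.52 and 5.89) were highest in cultures 4 and 1. C1qa, Csf1r and Fcgr3 were detected in culture 4 only. A strain difference was not tested apart from leukocytes in BALB/c cultures 1 and 3, where Cd68 was 7.93 and 6.02.

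Of the 35 splits of the 8 arrays into 4 and 4, the real one alone gave as many as 386 genes (highest other 348) and as many as 316 genes at least 2-fold (highest other 255). Both stand at 1 of 35, the smallest share this test can give. That counts against chance for these 2 counts but cannot exclude it. For probes 2 splits gave as many as the real 1511, and the highest other gave 2145, so chance is not excluded. That split exchanged BALB/c culture 2 and NOD culture 2, the 2 arrays nearest the other strain on the first component. For gene lists 2 splits gave as many as the real 7, with 7 in the highest other, and chance is not excluded.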

How the results depend on the processing

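The removal of BALB/c cultures in pairs, the deposited p-values, the robust background fit and the permutation test were chosen after seeing the data. The deposited p-values were used in the first fit made, and those below 1 step of the negative controls were set to 0 only after its results had been seen. Against 386 genes, 316 at least 2-fold, 1511 probes and 7 lists, counts were 216, 165, 775 and 4 for probes detected on all 8 arrays, 2438, 915, 10249 and 4 with array weights (whose estimation stopped before convergence), and 1427, 879, 5979 and 2 without BALB/c cultures 2 and 3. With the replicate block they were 129, 129 and 513, with 7 lists. The culture numbers do not pair the samples: correlations of deviations were -0.33, -0.64, -0.05 and 0.08, and 0 samples matched best with their own number. Median scaling and removal of BALB/c cultures 2 and 4, with or without the same probes kept, each called 4 lists, no filter on dim probes 210 genes at least 2-fold, and the deposited p-values 136 such genes, with 356 genes, 1194 probes and 6 lists. Of the 386 genes, 261 were also called with the deposited p-values and 376 with the robust background fit. Camera with an estimated correlation called 0 lists (2 at an unadjusted p under 0.05), the exact permutation test 0 (8 unadjusted) and fry 7, which differ from camera's: fry lost cell cycle (0.0508) and cholesterol synthesis (0.239) and gained the interleukin-1 and growth factor lists (0.0108 and 0.00906). The 8 lists at the exact test's smallest possible p of 0.0286 had an adjusted p of 0.0821. With 8 arrays this test could hardly call a list, so its 0 says little. With 1 culture left out, the ranges were 134 to 797 genes, 134 to 548 at least 2-fold, 460 to 3423 probes and 3 to 8 lists. The other settings stayed within 1.5 times. Of 1253 values of the 54 named genes, 1022 kept their side of the threshold, 231 lost the call and 0 reversed. Of 562 values of 23 lists, 532 kept it, 28 lost it and 2 gained it. The filter on all 8 arrays tests fewer probes; the cause of the other changes was not tested. Blocks by BeadChip were not run, as the files name none, so a batch that goes with the strains was not tested. Signal over background limits dim genes such as Cd274, whose difference was -1.97, and -0.32 with the deposited p-values.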

Other observations

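These values were looked at only after the main results had been seen. Of 12 tested probes for mitochondrially encoded transcripts, 1 differed: ND5 was lower in NOD (-0.97 ± 0.23 SE, adjusted p = 0.0368). Eif2s3y, a gene of the Y chromosome, was detected in BALB/c culture 3 (7.18) and on no other array, while Ddx3y, Kdm5d and Uty were detected on none.

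Genes of lists without a call also differed widely between cultures. Cxcl14, a chemokine, was 11.60 ± 0.41 in NOD and 8.27 ± 2.20 in BALB/c (difference 3.33 ± 0.94 SE, adjusted p = 0.0633). Contractile genes (camera adjusted p = 0.848), complement genes (0.573), homing molecules (0.573), immediate early genes (0.818, mean 0.57 but median -0.12) and genes of NOD diabetes loci (0.216) did not pass as lists. In these 5 lists no member passed over all genes, and adjusted over the list alone 1 immediate early gene was higher. The chondrocyte list had 1 tested gene, Sox5, with a difference of 1.73 (adjusted p = 0.139, higher adjusted over the list alone).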
